A study of Chenopodium quinoa with 9 samples.

How the data were processed

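Messenger RNA of field-grown quinoa (Chenopodium quinoa) was profiled in 3 organs, root, stem and leaf, with 3 libraries each. Per the labels' protocols, the plants were of a yellow bitter type and each biological replicate pooled 10 individuals out of 30. The labels call the pooled individuals strains, and these were taken here to be plants. The 3 organs were taken from the same pools, per the same protocols. RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit from 3 µg of total RNA. The libraries of an organ came from separate pools, per the labels' protocols, so p-values measure the spread between pools of plants. The kit's strandedness is not given in the sources used here, so reads of overlapping and antisense genes may not have been told apart.

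The authors deposited a table of raw read counts per gene and a table of FPKM values (fragment counts scaled by gene length and library size) for the same genes, per the file headers. Bowtie2 2.0.6 and TopHat2 2.0.12 are named in the submitters' processing notes. The counting tool, the genome build and the treatment of reads that fit several genes are not given in the sources used here. Quinoa is an allotetraploid with near-identical gene copies in its subgenomes, so the value of any one gene is uncertain where such copies shared reads. Each table has 54238 genes, of which 44776 have an AUR62 identifier and 9462 another identifier (non-AUR62 genes). All columns of both tables belonged to a sample of the series. The tables did not differ in which values were 0. Count divided by FPKM gave whole-number gene lengths within 0.01 bp for 100.0% of the 46576 genes with a count in any library. It also gave the library size that the authors used for FPKM, which was 0.773 to 1.21 times the total count of the same library. The FPKM values were thus not scaled by the total count alone.

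No source used here pairs the identifiers with gene names: 0 of the 54238 identifiers were found in the reference gene table of 58882 genes (RefSeq, assembly ASM168347v1). Gene lists for photosynthesis, cell walls, nutrient uptake, saponin synthesis and other functions, and lists of markers for other tissues, had been fixed as patterns on product descriptions and could not be applied. The planned set tests of these lists were not run, and no gene's function is stated. In their place, and chosen after the data were seen, camera tests compared non-AUR62 genes and the shortest and longest 20% of genes with all others, 9 tests in all. None of the 9 passed.

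Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were left out with filterByExpr, which kept 36685 genes (30769 AUR62 and 5916 non-AUR62). Libraries were scaled with TMM factors, and 1 robust quasi-likelihood model with tissue as its only factor was fitted to all 9 libraries, so that the tissues shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 in the quasi-likelihood F-test. A gene was named tissue-preferred when it was called and at least 2-fold higher in that tissue than in each of the others. It was named tissue-restricted, by a definition set after the data were seen, when its mean was at least 10 CPM (TMM-normalised counts, scaled to a common library size) in a tissue and under 1 CPM in every library of the others. CPM values are given as mean ± SD. The genes named in the comparisons followed a fixed rule that asked for a product description, with a fallback for identifiers without one, which applied here. For each comparison, the fallback considered called genes with a mean of at least 10 CPM in the higher tissue. These genes also had the same direction in all 3 same-numbered pairs. Of them it took the 2 per direction with the largest fitted fold change. Where every library of a tissue had 0 counts, the fold was computed against 3 counts per library and is a lower bound. Counts of genes that differed at least 2-fold take such genes at their bound. Bounds and Poisson intervals cover counting error only.

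The choices of test, filter, scaling and design, and the alternatives DESeq2 1.42.0, RLE and upper-quartile factors, other filters, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, fits of the 2 tissues alone, glmTreat and leaving out each library, were written down together with the rule for named genes before the data were examined. The protocols state that the organs came from the same pools, so the replicate number was taken to pair the libraries. Over genes, the deviations of the 9 same-numbered pairs of libraries from their tissue means correlated at -0.139 to 0.097, with 0 pairs above 0.1, so the pairing rests on the protocols and was not seen in the values. The edgeR procedure was tested on simulated data drawn from the real means, dispersions and library sizes, with 200 changed genes. A first run held only changes of 1 and 2 on the log2 scale, of which few were called, and changes of 4 were then added. For leaf against root, over 35866 genes, it called 81.8% of genes changed by 4 on the log2 scale, 34.3% of those changed by 2 and 0% of those changed by 1, with 2 false calls. For leaf against stem the shares were 78.8%, 34.3% and 0%, with 5 false calls. Stem against root, where nothing was changed, had 1 false call. With so few changed genes the adjusted threshold is stricter than in the real comparisons. Total counts per library ran from 16112021 to 24846346, so 3 counts corresponded to 0.121 to 0.186 CPM. Log2 CPM values for correlations, principal components and stem positions had a prior count of 2. Replicates differed by more than sampling noise: the chi-square per degree of freedom over genes was 12.6 for the closest pair, root replicates 1 and 2, and 320 for the most distant, stem replicates 1 and 3. No pair of replicates agreed within sampling noise, so none was treated as a library deposited more than once. That the replicates are separate pools rests on the protocols.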

Results

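The deposited data compared the transcriptomes of root, stem and leaf of yellow bitter quinoa, a grain crop of the amaranth family. Each organ was represented by 3 libraries, and each library by a pool of 10 plants. The total count per library ran from 16112021 to 18253046 in root, from 18719390 to 24846346 in stem and from 17554727 to 22035718 in leaf. A count was recorded for 39169 to 41347 genes in the root and leaf libraries and for 37466 to 40587 in the stem libraries. Across the study, 32388 of the 54238 genes had a count in every library and 7662 had none in any.

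The leading genes that together held 50% of counts numbered 1140 ± 180 in leaf, 1797 ± 493 in stem and 2384 ± 311 in root (SD, n = 3). All 3 leaf libraries lay below all 3 root libraries, which gave an exact permutation p of 0.10 (two-sided), the smallest that 3 against 3 unpaired libraries allow. The permutations of this paragraph did not keep the pairing of organs by pool, under which the smallest possible p is larger. The stem mean lay between them, and stem libraries overlapped those of both other organs (exact permutation p = 0.20 for both). Non-AUR62 genes took 7.97% ± 0.30 of counts in root, 7.46% ± 0.30 in stem and 6.86% ± 0.94 in leaf, and the libraries of the organs overlapped (exact permutation p from 0.20 to 0.40, where 0.10 is the smallest possible).

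The organs separated along the main axis of variation. The first principal component held 60.9% of the variance of log2 CPM and ran from root (-244.5 to -224.2) through stem (13.4 to 69.5) to leaf (186.9 to 210.1). Root libraries correlated with each other at r = 0.948 to 0.977 over genes and leaf libraries at 0.934 to 0.957. Root and leaf correlated at only 0.539 to 0.611, root and stem at 0.654 to 0.766, and leaf and stem at 0.720 to 0.865. Genes are not independent replicates, so these values describe the libraries and were not tested. The stem libraries were the least alike. Stem replicates 2 and 3 correlated at 0.894, while stem replicate 1 correlated with them at 0.806 and 0.780. Stem replicates 2 and 3 each correlated more highly with every leaf library, at 0.821 to 0.865, than with stem replicate 1. Stem replicate 1 also stood alone on the second component (16.5% of the variance), at -254.7 against -21.0 to 65.8 for the other 8 libraries. Without it, every comparison gave more calls, with 5460 genes higher and 4546 lower in stem than in root, 9004 and 9641 in leaf than in root, and 2642 and 2580 in leaf than in stem (edgeR).

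**Figure D1:**
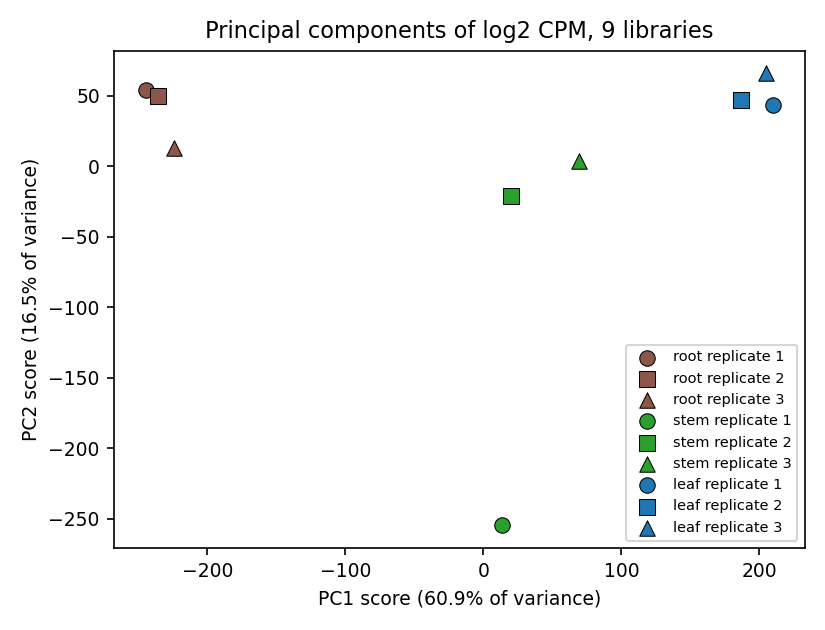
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by organ and with the replicate number as marker shape. Root, stem and leaf are ordered along the first component, and stem replicate 1 lies at -254.7 on the second.

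The comparison of leaf with root asked which genes distinguish the photosynthetic organ from the underground one, and it gave the most calls of the 3. Of the 36685 genes tested, 6987 (19.1%) were higher in leaf and 6845 (18.7%) were lower (edgeR, adjusted p below 0.05). Among these, 6098 of the higher and 5489 of the lower genes differed at least 2-fold. AUR62001880 reached 5927 ± 2071 CPM in leaf (SD, n = 3) with 0 counts in all 3 root libraries, at least 41054-fold higher (adjusted p = 5.2e-05). AUR62027587 reached 3513 ± 2006 CPM in leaf, again with 0 counts in root, at least 24338-fold higher (adjusted p = 0.000109). Both were also present in stem, at 1393 ± 338 and 350 ± 125 CPM. In the opposite direction, AUR62037366 was at 3834 ± 851 CPM in root and AUR62039860 at 3002 ± 592 CPM, with 0 counts in all leaf libraries. Their levels in root were at least 20844-fold and 16323-fold higher than in leaf (adjusted p = 0.000736 and 0.000926).

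Among the 5916 non-AUR62 genes tested, 710 were higher and 1207 lower in leaf than in root. As a set they did not pass a test against the other genes (camera with a preset correlation, adjusted p = 0.139 over 9 tests of gene classes; adjusted p = 0.878 with an estimated correlation). The set was chosen after the data were seen. Of the called genes, 50.5% were higher in leaf, against 42.0% with upper-quartile factors. The fit of root and leaf alone made 17677 calls in all, against 13832 in the fit of all 9 libraries. The number lower in leaf fell to 4538 without root replicate 1, 4310 without root replicate 2 and 4494 without leaf replicate 1.

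Stem differed from root in 4610 genes (12.6%) that were higher in stem and 3400 (9.27%) that were lower, of which 3967 and 2568 differed at least 2-fold. Both named genes that were higher in stem also had counts in leaf. AUR62001880 was at 1393 ± 338 CPM in stem and 5927 ± 2071 CPM in leaf, with 0 counts in root, at least 9653-fold higher (adjusted p = 0.000213). AUR62035864 was at 465 ± 315 CPM in stem and 3262 ± 1302 CPM in leaf, again with 0 counts in root, at least 3219-fold higher in stem (adjusted p = 0.00112). Both named genes that were lower in stem had counts in root alone. AUR62023869 was at 479 ± 123 CPM and AUR62002314 at 477 ± 260 CPM in root, with 0 counts in all 6 stem and leaf libraries. Root exceeded stem at least 3376-fold and 3356-fold for this pair of genes (adjusted p = 0.00048 and 0.00139).

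Non-AUR62 genes made up 494 of the genes higher in stem and 572 of those lower, and as a set they did not pass the camera test (adjusted p = 0.204; 0.921 with an estimated correlation). Leaving out any 1 of the root libraries lowered the numbers of genes higher and lower in stem by over 1.5 times, to 2535 and 1333 without root replicate 1, 2361 and 1212 without root replicate 2, and 3000 and 2048 without root replicate 3. Of the called genes, 57.6% were higher in stem, against 45.0% with limma on log2(FPKM + 1) and 47.2% when at least 1 FPKM in 3 libraries was also asked. The fit of stem and root alone made 5810 calls in all, against 8010 in the fit of all 9 libraries.

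Leaf and stem gave the fewest calls of the 3 comparisons. In leaf, 2356 genes (6.42%) were higher and 2108 (5.75%) lower than in stem, of which 2050 and 1949 differed at least 2-fold. Among the called genes that met the rule for naming, the largest fitted changes toward leaf were in genes of low level. AUR62028781 was at 19.4 ± 15.5 CPM and AUR62044157 at 17.7 ± 24.7 CPM in leaf. Both had 0 counts in stem, so their rank rests on fitted values. Leaf exceeded stem at least 137-fold and 124-fold for them (adjusted p = 0.0276 and 0.0207). The level of AUR62044157 rested on leaf replicate 1, at 46.2 CPM against 2.27 and 4.55 CPM in the other leaf libraries, and without it the bound was at least 24-fold. Without leaf replicate 3 the bound of AUR62028781 was at least 89-fold. The named genes that were higher in stem were higher still in root. AUR62039860 was at 344 ± 424 CPM in stem, with 0 counts in leaf, at least 1868-fold higher in stem (adjusted p = 0.00856), and at 3002 ± 592 CPM in root. Its stem values were 828, 40.2 and 162 CPM, and without stem replicate 1 the bound was at least 550-fold (adjusted p = 0.00338). AUR62029016 was at 935 ± 1560 CPM in stem and had 1 count over the 3 leaf libraries, a ratio of 46435 (8334 to 1834082 from the exact Poisson 95% interval of the leaf count; adjusted p = 0.0135). Its stem mean rested on stem replicate 1, at 2736 CPM against 26.2 and 41.1 CPM in the other stem libraries, and without stem replicate 1 the ratio was 1672 (300 to 66023 from the same interval; adjusted p = 0.00162). In root it was at 5908 ± 3166 CPM. Its call was lost without leaf replicate 1 (adjusted p = 0.078) and without leaf replicate 3 (adjusted p = 0.0623). That of AUR62028781 was lost without stem replicate 2 (adjusted p = 0.0537), leaf replicate 1 (0.0883) or leaf replicate 3 (0.0807), and with glmTreat (0.0624). That of AUR62044157 was lost when the 2 tissues were fitted alone (adjusted p = 0.0761) and with limma on log2(FPKM + 1) (0.0707, or 0.0685 with the FPKM filter).

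Non-AUR62 genes made up 147 of the genes higher in leaf than in stem and 308 of those lower (camera, adjusted p = 0.139; 0.878 with an estimated correlation). With the replicate block, the calls between leaf and stem fell to 1310 higher and 1169 lower. They fell to 725 and 702 without leaf replicate 1, to 793 and 860 without leaf replicate 3, and to 1256 and 1264 without root replicate 2. The number higher in leaf was 1080 without stem replicate 2 and 1451 without root replicate 1. Of the called genes, 52.8% were higher in leaf, against 43.4% with upper-quartile factors, 36.9% with glmTreat, 49.1% when the 2 tissues were fitted alone and 63.4% with limma on log2(FPKM + 1). The fit of the 2 tissues alone made 1571 calls in all, DESeq2 7838 and glmTreat 998, against 4464.

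**Figure D2:**
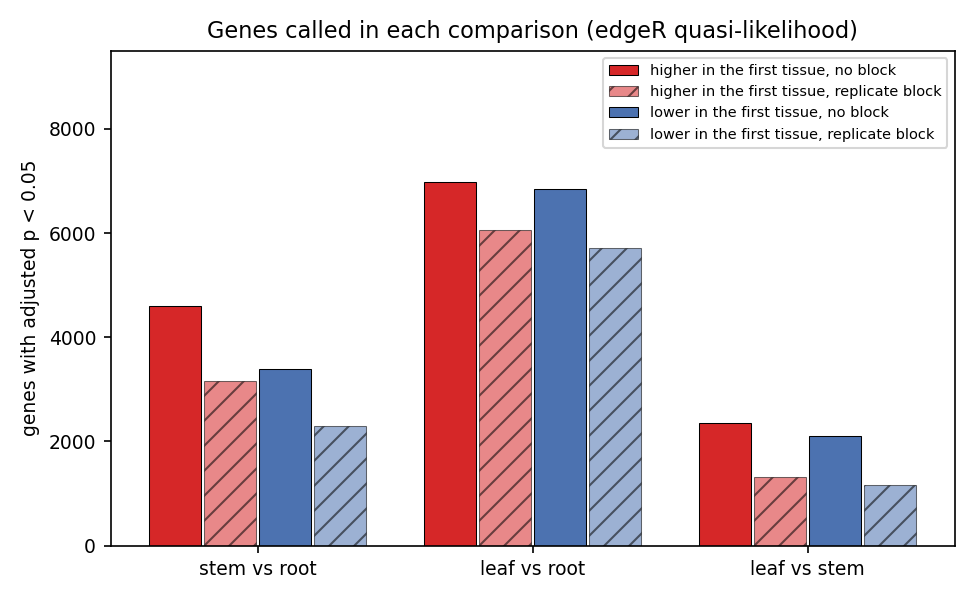
Number of genes called at an adjusted p below 0.05 (y axis) in each of the 3 comparisons (x axis), by direction, without the replicate block (plain bars) and with it (hatched bars). Among the plain bars, leaf against root has the highest, 6987 and 6845, and leaf against stem the lowest, 2356 and 2108; among the hatched bars these are 6056 and 5707, and 1310 and 1169.

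**Figure D3:**
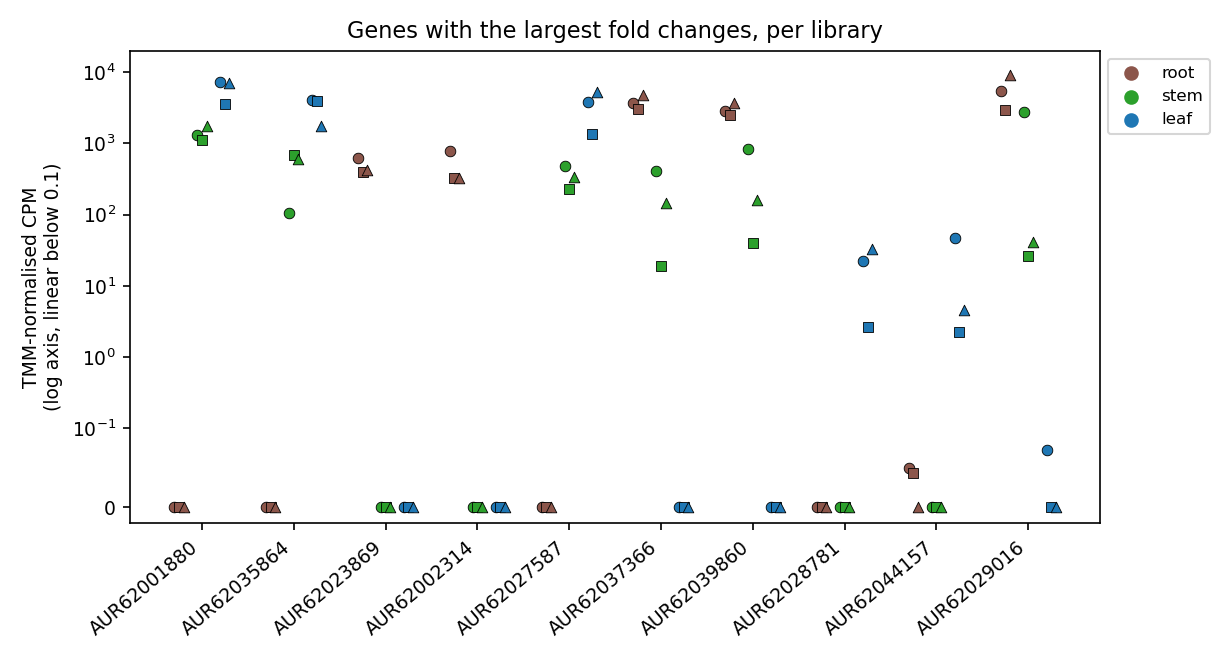
TMM-normalised CPM (y axis, log scale, linear below 0.1) of the named genes (x axis) in each library, coloured by organ, with circles, squares and triangles for replicates 1, 2 and 3. Points at the bottom are libraries with 0 counts, and AUR62029016 ranges from 26.2 to 2736 CPM over the stem libraries.

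Stem held the intermediate level for most genes that separated leaf from root. Among the 11592 genes called and at least 2-fold different by the fitted value between leaf and root, the mean stem level lay between both organs for 83.8%, beyond root for 6.2% and beyond leaf for 9.9%. On a scale from 0 (root) to 1 (leaf) in log2 CPM, the median stem position was 0.585, with quartiles at 0.361 and 0.787. The genes were chosen on the root and leaf libraries that set the ends of this scale. The 6100 genes higher in leaf had a median of 0.597 and the 5492 genes higher in root a median of 0.562. The median was 0.533 in stem replicate 1, 0.592 in stem replicate 2 and 0.645 in stem replicate 3. Stem was at an intermediate level for fewer of these genes in replicate 1 (63.1%) than in replicates 2 and 3 (78.3% and 78.8%).

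Gene sets preferred by a single organ were large in root and leaf and small in stem. There were 2005 root-preferred, 1772 leaf-preferred and 150 stem-preferred genes. Each set is the overlap of a pair of lists that share the libraries of an organ. Independent lists of the same sizes would share 385, 341 and 212 genes. In 10 simulations with no effect, lists filled to the same sizes with the genes of smallest p shared 1077 to 1125 genes for root, 972 to 1014 for leaf and 697 to 755 for stem, a comparison added after the data were seen. These lists had no adjusted p or 2-fold cut, so they show only that lists sharing an organ's libraries overlap more than independent lists. By the rule for preferred genes itself, the same simulations gave 0 genes in every organ. Each made at most 1 call over all 3 comparisons, so no gene could be called in a pair of them. The 0 is therefore no baseline for the overlap. Part of the overlap in root and leaf may still come from the shared libraries. For stem, the 150 genes lay below the simulated lists, which had no adjusted p or 2-fold cut, and below independent lists. Independent lists are too low a baseline where libraries are shared. The order against independent lists depended on the fit, with 333 genes against 274 without stem replicate 3, 68 against 61.2 without leaf replicate 1 and 159 against 105 with limma on log2(FPKM + 1). The root-preferred genes took 10.3% ± 1.2 of counts in root, 2.14% ± 0.39 in stem and 1.30% ± 0.21 in leaf (SD, n = 3). Leaf-preferred genes took 22.8% ± 4.3 in leaf, 7.0% ± 2.49 in stem and 2.10% ± 0.10 in root. Stem-preferred genes took 0.51% ± 0.06 in stem, 0.14% ± 0.00 in root and 0.06% ± 0.01 in leaf. These sets were chosen on the same libraries, so the shares describe their size and are not independent evidence of the differences. The leaf-preferred genes had a median level of 52.3 CPM in leaf, and the root-preferred genes one of 14.2 CPM in root. Non-AUR62 genes made up 19.7% of the root-preferred, 17.3% of the stem-preferred and 6.0% of the leaf-preferred set, and 5916 of all 36685 tested genes. These shares were not tested.

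With the replicate block, the sets held 1084 leaf-preferred and 83 stem-preferred genes, of which 1054 and 77 were also in the unblocked sets. Stem-preferred genes numbered 242 without stem replicate 1, 333 without stem replicate 3, 74 and 63 without root replicates 1 and 2, and 68 and 72 without leaf replicates 1 and 3. Root-preferred genes fell to 991 and 889 without root replicates 1 and 2. Leaf-preferred genes fell to 589 and 644 without leaf replicates 1 and 3, to 867 without stem replicate 2, and to 1174 and 1011 without root replicates 1 and 2.

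A smaller group was restricted to an organ, with a mean of at least 10 CPM there and under 1 CPM in each library of the others. It held 99 genes in root, 37 in leaf and 8 in stem. The highest mean among them was 479 CPM for a root gene, 347 CPM for a leaf gene and 44 CPM for a stem gene. All 99 root-restricted genes were also root-preferred, as 34 of the 37 in leaf were leaf-preferred and 3 of the 8 in stem stem-preferred. Both definitions used the same libraries, so this overlap is not independent evidence. Without stem replicate 1, 152 genes were restricted to root and 56 to leaf, and without stem replicate 3 there were 58 in leaf. The stem number ranged from 4 without stem replicate 1 to 21 without root replicate 3. It was 15 without root replicate 1, 14 without root replicate 2, 13 without stem replicate 3 and 15 without leaf replicate 1. The rule asks for under 1 CPM in every library of the other organs. A fit without such a library asks less, which by itself tends to raise the number.

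**Figure D4:**
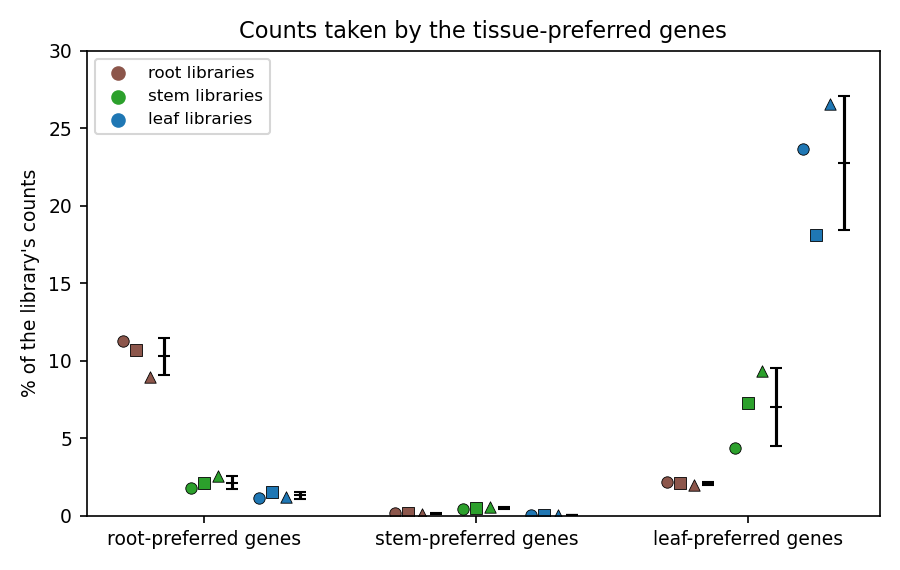
Share of each library's counts (y axis, percent) taken by the 2005 root-preferred, 150 stem-preferred and 1772 leaf-preferred genes (x axis). Points are libraries coloured by organ, with circles, squares and triangles for replicates 1, 2 and 3, and bars give the mean ± SD of 3 libraries; the leaf-preferred genes take 22.8% of leaf counts.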

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

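The directions and calls of the named genes held in 231 of the 240 gene and alternative combinations, and in the other 9 the direction held while the adjusted p (edgeR or limma) rose above 0.05. These were AUR62028781 (with glmTreat, and without stem replicate 2, leaf replicate 1 or leaf replicate 3), AUR62044157 (with the 2 tissues alone, and with limma on log2(FPKM + 1) under both filters) and AUR62029016 (without leaf replicate 1 or leaf replicate 3), with the highest adjusted p at 0.0883. Counts of genes stayed within 1.5 times under RLE and upper-quartile factors and without a filter. Upper-quartile factors moved the median log2 fold change of all genes from -0.07 to -0.24 for leaf against root and from -0.07 to -0.17 for leaf against stem, and the share of called genes higher in leaf from 50.5% to 42.0% and from 52.8% to 43.4%. The cause of each change below was not tested, except that glmTreat asks for more than a 2-fold change and fits without a library have fewer samples. With DESeq2, the genes higher and lower in leaf than in stem numbered 4167 and 3671, the stem-preferred 367 and the leaf-preferred 2665. With the replicate block, these were 1310, 1169, 83 and 1084, and the block moved no other count of called or preferred genes by over 1.5 times (restricted genes were not fitted with it). With the 2 tissues compared alone they were 771, 800, 78 and 704. With glmTreat, 1922 genes were higher and 961 lower in stem than root, 4204 and 3229 in leaf than root, and 368 and 630 in leaf than stem, with 778 root-preferred, 38 stem-preferred and 290 leaf-preferred genes. The stem-restricted genes numbered 5 with at least 1 CPM in 3 libraries and 13 on the FPKM scale. In alternatives chosen after seeing the data, a mean of at least 5 CPM in the tissue gave 186 root-restricted, 20 stem-restricted and 81 leaf-restricted genes. Under 0.5 CPM elsewhere gave 2 for stem and 18 for leaf. Over the 500 most variable genes the lowest correlation within a tissue was 0.502 and the highest between tissues 0.743, against 0.780 and 0.865 over all tested genes. Leaving out each library in turn gave 2361 to 5460 genes higher and 1212 to 4546 lower in stem than root, 5204 to 9004 and 4310 to 9641 in leaf than root, and 725 to 2642 and 702 to 2580 in leaf than stem. It gave 889 to 2660 root-preferred, 63 to 333 stem-preferred and 589 to 1835 leaf-preferred genes, and 68 to 152 root-restricted, 4 to 21 stem-restricted and 36 to 58 leaf-restricted genes. In the simulation of leaf against root, 0% of genes changed by 1 on the log2 scale were called. Few genes were changed there, so the adjusted threshold was stricter than in the real comparison. The real comparison did call smaller differences. Of its 6987 genes higher in leaf 6098 differed at least 2-fold, and of its 6845 lower genes 5489 did. The simulated share therefore cannot tell how many small differences went uncalled in the real data, and some may have. The planned set tests on gene lists, fry among them, were not run, because the identifiers were not paired with descriptions.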

Other observations

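The tests of the length trend as the whole cause and of plant pool 1 were chosen after the values concerned had been seen; the other tests were written down before their results were seen. The departure of stem replicate 1 was itself noticed in the data. At the thresholds used for preferred genes, 3433 genes were lower in root than in both other organs, 1613 were lower in leaf and 178 were lower in stem. The matching numbers of preferred genes were 2005, 1772 and 150, and the differences between these counts were not tested. The most abundant gene differed between the libraries of each organ, a feature singled out after its values were seen. In root it was AUR62029016 in replicates 1 and 3 and AUR62010294 in replicate 2. In leaf it was AUR62023435 in replicates 1 and 2 and AUR62026058 in replicate 3. AUR62003223 was the most abundant gene in stem replicates 1 and 2, with 1.46% and 2.07% of their counts, but held 0.186% in stem replicate 3. There the most abundant gene was AUR62041293, with 2.26%, against 0.166% and 0.454% in stem replicates 1 and 2.

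Stem replicate 1 stood apart from the other stem libraries. In it, 786 genes (12.8% of its counts) were at least 4-fold higher than in both other stem libraries, and 467 were at least 4-fold lower; for stem replicate 2 the numbers were 96 higher and 113 lower, and for stem replicate 3 they were 141 and 244. Root or leaf tissue mixed into the pool could raise a gene only toward the level of its source. Of the 786 genes, 88.7% lay above every root and leaf library, which argues against such a mixture for those genes. For the matching genes of stem replicates 2 and 3 this share was 46.9% and 59.6%. Of the 786 genes, 521 were higher in root than in leaf, against 68 of the 96 for stem replicate 2 and 56 of the 141 for stem replicate 3. A lean toward root was thus not particular to stem replicate 1. Without the 100 most abundant genes of stem replicate 1, its higher correlation with another stem library was 0.803, against 0.806 with them. The least alike of the other pairs of one tissue was at 0.894 without these genes. The correlation weighs all 36685 tested genes alike, so leaving out 100 could hardly move it and does not decide whether abundant genes had a part. A length trend alone did not account for the departure, since 725 genes were at least 4-fold higher after it was removed (96 and 136 for the other stem libraries). A partial trend stays open, with a Spearman correlation of -0.196 with gene length against -0.204 to 0.188 in the other libraries. A difference of plant pool 1 shared by its organs would move root and leaf replicate 1 as well, but the higher of these correlations over genes was 0.032. This holds only if the replicate number is the pool number, which was not seen in the values. The deviations of stem replicate 1 and root replicate 3 correlated at 0.216. This was the highest value among differently numbered pairs from different organs, which ran down to -0.181. Both libraries also had the most negative correlations with gene length, at -0.196 and -0.204, so a shared length trend may have a part. With leaf libraries, the deviations of stem replicate 1 correlated at -0.122 to 0.075. These values do not decide whether organs shared a pool difference under another numbering, which stays open. A different part or stage of the stem, tissue other than root or leaf, a pool difference confined to stem, a library batch and a wrongly labelled library stay open and were not tested.

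Of the 10 splits of the 6 libraries of a comparison, 1, the real one, called as many genes in each case: 8010 against at most 0 for stem and root, 13832 against at most 0 for leaf and root, and 4464 against at most 7 for leaf and stem. The splits that part all same-numbered pairs had the same highest values. With 10 splits the share cannot fall below 0.1, so these counts are too few for a test at 0.05.

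More pairs of genes with consecutive identifier numbers shared a preference than in shuffles. Of 23086 pairs of tested AUR62 genes with consecutive numbers, 236 were preferred in the same organ, against a mean of 131 and a highest value of 170 in 10000 shuffles of the preferences. Root gave 123 of the pairs, leaf 110 and stem 3. The number fell to 195 at a distance of 2 and to 119 at a distance of 10. If identifiers were numbered along the genome, which was not checked here, tandem copies or neighbouring genes with a common expression pattern may be a candidate explanation. Reads shared between near-identical copies would give the same pattern and were not tested.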
